A study of Mus musculus with 8 samples.

How the data were processed

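Messenger RNA bound to GFP-tagged ribosomal protein L10a (immunoprecipitate) and total RNA (input) of the anterior hypothalamus were measured in mice of the lines PACAP GFP and BDNF GFP. Per the labels, the tissue was dissected from 0.5 mm sections, the pull-down used a mixture of monoclonal antibodies to EGFP, complementary DNA was amplified with Ovation RNA-Seq V2, libraries were made with Ovation Ultralow DR Multiplex, and sequencing was on an Illumina HiSeq4000. Per the submitters' processing notes the genome build was mm9. The aligner, the counting tool and the gene annotation are not given in the sources used here.

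The deposited table lists 8863 genes with linear RPKM (reads scaled by gene length and library size) for each of the 8 libraries, per the file headers. It also holds deposited raw counts per gene and library. Every column was mapped to a sample by its label (0 unmapped), and no library was a copy of another. The lowest count in any library was 1 and the lowest value over genes of a gene's highest RPKM was 1.25, so genes with few reads had been left out of the table before it was deposited, by a rule not given in the sources used here. The table is thus no complete list of genes, and a gene missing from it is not shown to be absent from the tissue. Gene symbols were matched to a RefSeq table (98.6% of symbols), whose build differs from mm9, so no coordinates are reported. There were 9 symbols listed on 2 lines of the table.

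The depth per library, as the sum of deposited counts, ran from 8080295 in BDNF immunoprecipitate 2 to 16039931 in BDNF input 2. The counts were compared with the RPKM of the same gene over the 8 libraries, after a factor per library taken from genes with at least 50 counts. They were proportional within 0.1 log2 units in 2767 genes (31.22%): in 50.28% of 4875 genes with 1 RefSeq transcript and in 7.14% of 3808 genes with 2 or more. For most genes the counts and the RPKM were not proportional, and what the counts hold there was not established, so the tests used RPKM. The median of the mean count was 1306 in proportional genes and 70.0 in the others.

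Values were analysed as log2(RPKM + 1) in R 4.3.3 with limma 3.58.1, using a trend in the prior variance. Genes needed at least 1 RPKM in 2 or more libraries, which all 8863 passed. A single fit gave 4 group means (line by fraction) from all 8 libraries with a shared spread, without a block. Contrasts were immunoprecipitate against input in each line, the mean of both (the joint comparison), their difference, input against input, and immunoprecipitate against immunoprecipitate. P-values were adjusted by Benjamini-Hochberg over all genes and called below 0.05. Groups, comparisons, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

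Whether the replicate numbers pair libraries was checked from the differences between replicates of each group. Over genes, these correlated at r = 0.472 between immunoprecipitate and input of the PACAP line and 0.405 of the BDNF line, but also at 0.698 between the inputs and 0.382 between the immunoprecipitates of the lines, and at 0.436 and 0.457 across line and fraction. Libraries of the same number thus deviated together, but about as much across line and fraction as within a line, and less than the inputs did, so the numbers mark a batch common to both lines and pairing within a line was not shown beyond it. A fit with line and replicate number as a block was run as an alternative, and its values are given beside the results.

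Gene lists were written from general knowledge of cell types. They covered genes of GABAergic, glutamatergic and other transmitter neurons, neuropeptides, hormone and pyrogen receptors, temperature-sensitive channels, pan-neuronal and immediate early genes, astrocytes, oligodendrocytes and their precursors, microglia, ependyma and choroid plexus, striatum, cortex with hippocampus and thalamus, hypothalamic transcription factors, ribosomal proteins and nuclear genes of oxidative phosphorylation. Some genes sit in more than one list: Fezf1 is in the glutamatergic and hypothalamic lists, Penk in the neuropeptide and striatal lists, and Adcyap1 and Bdnf in the neuropeptide list. The 18 lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Vascular, blood and nuclear noncoding lists had fewer measured genes and were not tested as lists. None of the listed leptomeningeal or mitochondrially encoded genes was in the table. Members were counted as higher or lower over all genes and again adjusted over the list alone.

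Named genes were, per comparison and direction, the 10 with the largest change among called genes that had a mean of at least 5 RPKM in the higher group and no overlap between the groups, filled at an unadjusted p under 0.05 where fewer passed. Adcyap1, Bdnf, Rpl10a and members of each list with the lowest p were named whatever their values. Unnamed gene models were counted and not named. A few genes that met these rules are not reported here.

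The analysis was repeated with pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, quantile normalisation, centring on the median, limma without trend, library weights, leaving out each library, the 4 libraries of a line alone, and the block. Chosen after the data were seen were a block on the replicate number shared by both lines, limma on the 2767 genes with proportional counts, edgeR 4.0.16 and DESeq2 1.42.0 on the counts of those genes, edgeR on all deposited counts, and list medians between the lines within a replicate number. Further tests drew 10000 random lists and used genes of at least 20 RPKM for carry-over of input RNA.

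The methods were tested on simulated data of the same size, with 50 genes changed at each of 4 sizes. Without the block, the PACAP comparison recovered 0, 48, 90 and 98% of changes of 1, 2, 3 and 4 log2 units with 0% false calls, and the joint comparison 12, 86, 98 and 100% with 0%. With the block the values were 36, 98, 100 and 100% with 6.7% false calls, and 78, 100, 100 and 100% with 5.5%. With the shared block they were 36, 100, 100 and 100% with 6.7%, and 82, 100, 100 and 100% with 3%. On 2767 genes of simulated counts in the PACAP comparison, edgeR recovered 6, 58, 80 and 98% with 2.4% false calls and DESeq2 12, 72, 88 and 98% with 16.7%. Of 100 random lists of 15 genes without any shift, camera called 4% at the preset and 1% at the estimated correlation. With 10 lists shifted by 1 log2 unit it found all 10 at both, with 3 other lists among 13 calls at the preset correlation and 1 other among 11 at the estimated correlation. The simulations drew independent genes. Those for limma gave each gene 1 replicate shift, the same in every line and fraction, so the block was right by construction. In the data the replicate differences correlated at 0.382 to 0.698 between groups. The shares of false calls with the block thus need not hold for the real calls.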

Results

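Per its title, the study set out to profile warm-sensitive neurons, preoptic cells that respond to warming, by the RNA on their ribosomes. Translating ribosome affinity purification pulls down GFP-tagged ribosomes from one cell population of a dissected tissue together with the messenger RNA they hold. The anterior hypothalamus was taken from mice of the strain C57Bl6/J in lines labelled PACAP GFP and BDNF GFP, for the peptide product of Adcyap1 and the neurotrophin product of Bdnf. From each line, total RNA of the tissue (input) and RNA bound to the tagged ribosomes (immunoprecipitate) were sequenced, each in replicates numbered 1 and 2, which gave 4 groups of 2 and 8 libraries in all. Libraries are named here by line, fraction and number. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

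The table held 8863 genes, each with a linear RPKM and a raw count per library. Counts summed to 9490686 in PACAP input 1, 9265765 in PACAP immunoprecipitate 1, 13436016 in PACAP input 2 and 15477929 in PACAP immunoprecipitate 2. In the BDNF line the sums were 12428584 for input 1, 12292291 for immunoprecipitate 1, 16039931 for input 2 and 8080295 for immunoprecipitate 2. Fold changes are differences of log2(RPKM + 1) with their standard error (SE), a scale that understates changes of genes with low values, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over all 8863 genes. Where the fit with the replicate number as a block (each input with the immunoprecipitate of its own line and number) changed a call, its adjusted p is given as the blocked value. Every SE is from the fit without a block, also where a blocked value stands beside it, and does not belong to that value. The edgeR fit on all deposited counts had no block. For most genes the counts were not proportional to the RPKM and what they hold was not established. A call lost with edgeR there may thus be lost through the counts.

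The first principal component held 39.7% of the variance of the 8 libraries and placed all 4 immunoprecipitates above all 4 inputs. Replicate numbers separated on the second, which held 30.1%, in both fractions and both lines. Between the numbers 1743 genes differed in a fit with the replicate number as one term for both lines, 707 higher and 1036 lower in replicate 2. Camera called 8 lists lower in replicate 2 and none higher, each with adjusted p = 0.606 with an estimated correlation. They were ribosomal proteins at a median of -0.56 (adjusted p = 2.22e-12), oxidative phosphorylation at -0.60 (4.39e-10), oligodendrocytes at -0.86 (0.00183), astrocytes at -1.11 (0.00186), GABAergic genes at -0.70 (0.0122), hypothalamic transcription factors at -0.81 (0.0316), and microglia at -1.49 and oligodendrocyte precursors at -1.04 (0.0464 each), so the change was not one of glia alone.

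**Figure D1:**
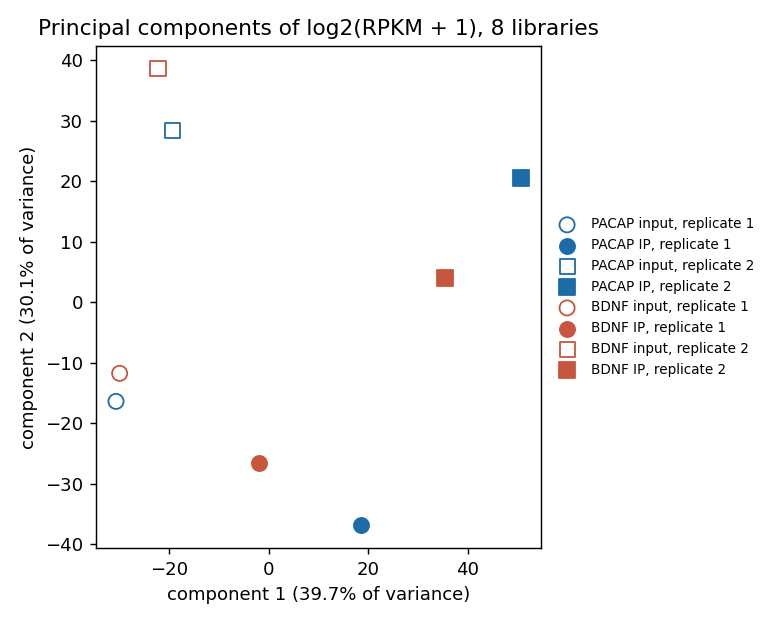
The 8 libraries on the first and second principal components of log2(RPKM + 1), which hold 39.7% and 30.1% of the variance; each point is a library, marked by line, fraction and replicate number. Immunoprecipitates lie above inputs on the first component and replicate 2 above replicate 1 within each group on the second.

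The joint comparison tested the mean of the changes of both lines, with 4 immunoprecipitates against 4 inputs, which does not ask for a change in each line. Both genes that name the lines rose. Adcyap1 rose by 2.50 ± 0.41 (± SE, adjusted p = 0.0248), from between 2.19 and 5.52 RPKM in the inputs to between 13.8 and 49.999 RPKM in the immunoprecipitates. Bdnf rose by 1.93 ± 0.37 (adjusted p = 0.0411), from between 1.64 and 2.35 RPKM to between 4.55 and 20.2 RPKM. Each was higher in the immunoprecipitate of all 4 pairs, the lines not named for it included. The Adcyap1 call ended without PACAP input 1 (adjusted p = 0.0759), PACAP input 2 (0.0627), PACAP immunoprecipitate 2 (0.058), BDNF input 1 (0.0638) or BDNF immunoprecipitate 2 (0.0638). The Bdnf call ended without PACAP input 1 (0.126), PACAP input 2 (0.111), PACAP immunoprecipitate 2 (0.0799), BDNF input 1 (0.0921), BDNF input 2 (0.0975) or BDNF immunoprecipitate 2 (0.16), and with a pseudocount of 5 (0.0508). With edgeR on all deposited counts the adjusted p was 0.125 for Adcyap1 and 0.123 for Bdnf. Blocked values were 0.000168 and 0.00239 in that order, and a block shared by both lines gave 0.00124 and 0.00235. Over the 8 fits that left out 1 library, the change ran from 2.06 to 2.95 for Adcyap1 and from 1.61 to 2.25 for Bdnf. The fits that left out a library had no block, here and below. Each thus set fraction partly against replicate number, and a call may end in them through that batch.

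Among the other genes that rose most, Gng8, a gamma subunit of heterotrimeric G proteins, changed by 3.34 ± 0.34 (adjusted p = 0.00308). Ucn3, the peptide urocortin 3 of the corticotropin-releasing factor family, rose by 2.37 ± 0.31, and Nxph4, a secreted ligand of neurexins, by 2.28 ± 0.27. Nrn1, the neurite growth factor neuritin, gained 2.04 ± 0.25 and Samd3 gained 2.42 ± 0.25. These 5 calls held in each of 8 fits that left out 1 library, although edgeR on all deposited counts gave adjusted p = 0.0652 for Samd3 and 0.0916 for Nrn1. Emx2, a homeodomain transcription factor, rose by 2.07 ± 0.32 (adjusted p = 0.021), a call that ended without PACAP input 2 (0.0517), BDNF input 2 (0.0735) or BDNF immunoprecipitate 2 (0.0995). Efcab10 rose by 2.06 ± 0.39 (adjusted p = 0.0379) and was lost without PACAP input 1 (0.114), PACAP immunoprecipitate 1 (0.0539), PACAP input 2 (0.0895), BDNF immunoprecipitate 1 (0.0746), BDNF input 2 (0.105) or BDNF immunoprecipitate 2 (0.154), and with edgeR on the genes with proportional counts (0.0581). Fezf1, a zinc-finger transcription factor of forebrain development, rose by 1.76 ± 0.28 (adjusted p = 0.0238). Its call ended without PACAP input 1 (0.088), PACAP input 2 (0.0574), BDNF input 1 (0.0612), BDNF immunoprecipitate 1 (0.0524), BDNF input 2 (0.0797) or BDNF immunoprecipitate 2 (0.0902), and with edgeR on all deposited counts (0.148).

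Of the genes that fell most, several belong to myelin. Ermn changed by -3.74 ± 0.39 and Mobp by -3.56 ± 0.25 (adjusted p = 0.000652). Olig1, a transcription factor of the oligodendrocyte lineage, changed by -3.60 ± 0.52 (adjusted p = 0.0132), a call lost without PACAP input 1 (0.0502). Efhd1, a calcium-binding mitochondrial protein, changed by -3.95 ± 0.33 (adjusted p = 0.00108), and Fabp7, a fatty-acid-binding protein of astrocytes and radial glia, by -3.37 ± 0.37. Lrrc17 changed by -3.64 ± 0.27 (adjusted p = 0.000671) and Pwwp2a, a chromatin protein, by -3.56 ± 0.45. The neuropeptide gene Sst, which encodes somatostatin, changed by -3.46 ± 0.59 (adjusted p = 0.0284) and Cdr1 by -3.57 ± 0.61 (adjusted p = 0.0284). The Sst call ended without PACAP input 1 (0.0866), PACAP input 2 (0.0527), PACAP immunoprecipitate 2 (0.0566), BDNF input 1 (0.0638) or BDNF immunoprecipitate 2 (0.137). The Cdr1 call ended without the same libraries, at 0.0866, 0.0565, 0.0723, 0.0638 and 0.0513 in that order.

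**Figure D2:**
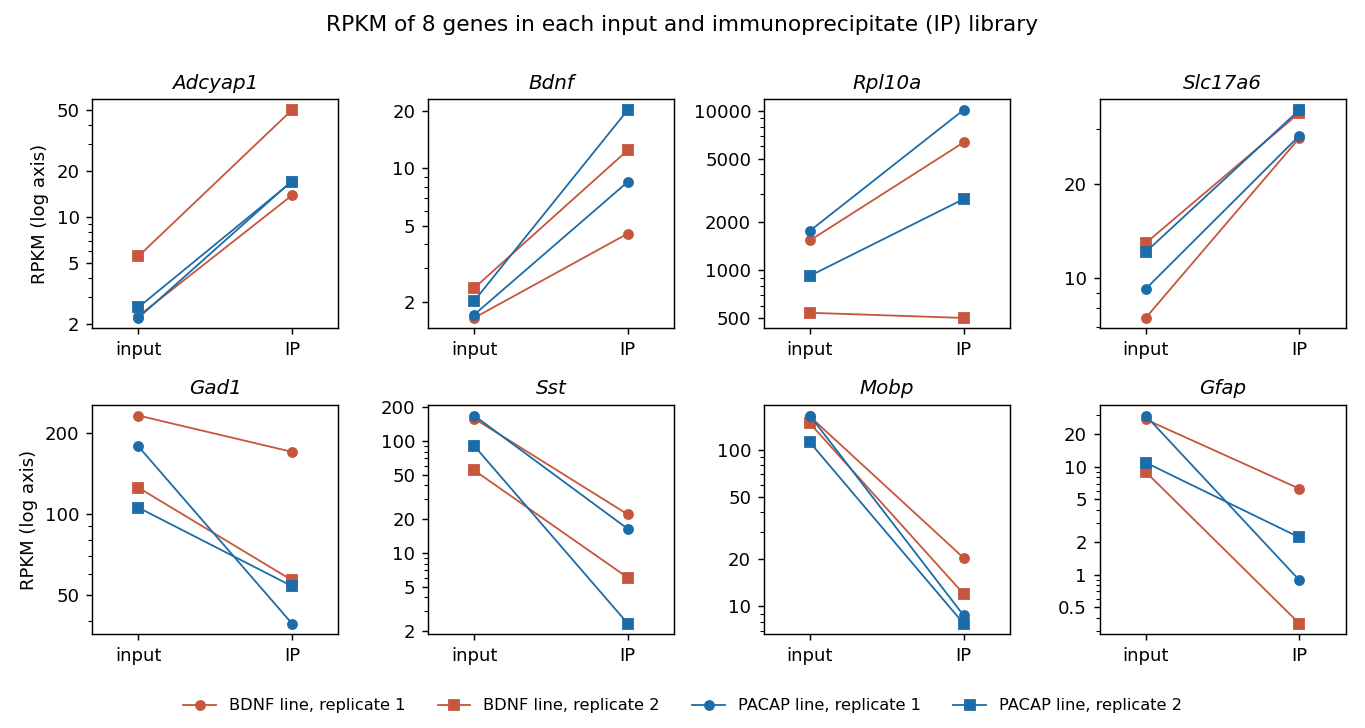
RPKM on a log axis of 8 genes in each of the 8 libraries, inputs and immunoprecipitates of both lines, with a line joining the pair of each replicate number. Adcyap1, Bdnf and Slc17a6 are higher in the immunoprecipitate of every pair, Sst, Mobp and Gfap are lower in every pair, and Rpl10a is higher in 3 of the 4 pairs.

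The transmitter lists moved apart. Of 5 measured members of the glutamatergic list, 4 rose: Slc17a6, the vesicular glutamate transporter VGLUT2, by 1.52 ± 0.25 (adjusted p = 0.0259), Nrn1, Fezf1, and Nhlh2, a basic helix-loop-helix transcription factor, by 1.64 ± 0.26 (adjusted p = 0.0213). The remaining member, Slc17a8, changed by -0.42 (adjusted p = 0.378). With edgeR on all deposited counts none of these 4 passed (0.0916 for Slc17a6 and Nrn1, 0.148 for Fezf1, 0.119 for Nhlh2), and DESeq2 tested 0 of the 5, as it was run only on genes with proportional counts. The list median was 1.64 (camera adjusted p = 2.2e-05, and adjusted p = 0.337 with an estimated correlation), with 4 members higher when adjusted over the list alone. All 9 measured members of the GABAergic list lay below 0, at a median of -1.17 (adjusted p = 0.000326, and adjusted p = 0.38 with an estimated correlation). Dlx5, a transcription factor of inhibitory neurons, changed by -2.40 ± 0.48 (adjusted p = 0.0445, but 0.0943 with edgeR), and 6 members fell when adjusted over the list alone. With the block 7 members fell, among them Gad1, which makes GABA, at -1.17 (blocked value 0.00969), and Slc32a1, which loads it into vesicles, at -1.64 (0.00514). Not called with or without it were Gad2 at -0.32 (adjusted p = 0.494, blocked value 0.28) and Gabrg1 at -0.09 (adjusted p = 0.906, blocked value 0.834). Gad2 stayed between 290 and 406 RPKM in the immunoprecipitates, against 387 to 441 RPKM in the inputs. Of 4 genes of other transmitters none passed in limma (4 at unadjusted p under 0.05; 0 with edgeR, 2 of 3 tested with DESeq2) and the list test gave adjusted p = 0.233. Adjusted over the list alone, 1 was higher and 3 were lower. With the block, Chat, the acetylcholine-making enzyme, fell by 1.39 (0.00679), Th, the rate-limiting enzyme of catecholamine synthesis, fell by 1.44 (0.0286, but 0.0606 with a block shared by both lines) and Nos1, which makes nitric oxide, rose by 0.80 (0.0275).

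Of 19 neuropeptide genes, 3 rose (Adcyap1, Bdnf, Ucn3), 2 fell and 14 did not pass. Gnrh1, which encodes gonadotropin-releasing hormone, fell by 2.97 ± 0.52 (adjusted p = 0.0286), and Sst fell as well. With edgeR 2 of these 5 passed, Ucn3 and Sst, and Gnrh1 was at 0.143. Adjusted over the list alone, 6 rose and 3 fell, and the list test gave adjusted p = 0.0596 at a median of 0.62 (blocked value 0.0373, and adjusted p = 0.409 with an estimated correlation). With the block 7 rose and 4 fell, adding Ghrh, growth hormone-releasing hormone, at 2.33 ± 0.82 (0.000358), Trh, thyrotropin-releasing hormone, at 1.44 ± 0.57 (0.00327), Cck at 0.96 (0.00936) and Scg2 at 0.68 (0.0422) on the higher side, and Avp, vasopressin, at -2.09 ± 0.84 (0.0107) and Penk, an enkephalin precursor, at -1.30 (0.0187) on the lower. Of 18 measured receptors for hormones and pyrogens and 7 measured temperature-sensitive channels none passed in limma, nor when adjusted over the list alone. At unadjusted p under 0.05 in limma there were 4 receptors and 0 channels. With edgeR 0 passed in either list. DESeq2 called 1 of 8 receptors tested, and 0 channels were tested with it. Receptors and channels left out of the deposited data were not tested, so these results cover the measured members only. The medians of receptors and channels were -0.26 and -0.38. They were -0.06 and -0.00 with quantile normalisation, and -0.18 and -0.30 with libraries centred on the median. The list tests gave adjusted p = 0.267 for each. With the block the bombesin-like receptor Brs3 rose by 0.98 (0.0422) and the dopamine receptor Drd2 fell by 0.88 (0.0379), while no channel was called. The channel nearest to the threshold was Kcnk10 at -0.42 (adjusted p = 0.337). Some channels had low values over the 8 libraries: Orai1 at 0.37 to 3.98 RPKM, Kcnk10 at 1 to 2.64 and Trpm2 at 0.7 to 3.56. The scale used understates changes at such values, so a missing call there does not show that a channel was unchanged. Trpc5 at 8.51 to 18.55 RPKM and Kcnk2 at 6.69 to 18.97 lay higher.

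Glial lists lay on the lower side. All 9 measured oligodendrocyte genes were below 0, 7 fell and 2 (Cldn11 at -2.50 and Trf at -2.84) did not pass, and the median was -2.84 (adjusted p = 4.32e-13, and adjusted p = 0.368 with an estimated correlation). Mbp, myelin basic protein, changed by -2.46 and Mog by -2.78. With edgeR 5 of the 7 passed and Mbp (0.798) and Cnp (0.12) did not. All 9 fell when adjusted over the list alone and with the block. Of 7 astrocyte genes, S100b changed by -2.50 ± 0.41 (adjusted p = 0.0259) and 6 did not pass. Gfap, the astrocyte filament protein, was at -2.70 (adjusted p = 0.0529, blocked value 0.001) and Glul, glutamine synthetase, at -1.77 (adjusted p = 0.0522, blocked value 0.000662). All 7 fell when adjusted over the list alone and with the block, and the list median was -2.10 (adjusted p = 3.78e-06, and adjusted p = 0.38 with an estimated correlation). In the oligodendrocyte precursor list Olig1 and Olig2 fell (Olig2 at -3.18), whereas C1ql1, a secreted C1q-like protein, was at 1.82 ± 0.46 (adjusted p = 0.0772, blocked value 0.00108); the list test gave adjusted p = 0.162. Adjusted over that list alone, 1 gene rose and 2 fell. Of 3 microglial genes none passed in limma (2 at unadjusted p under 0.05; 0 with edgeR, 1 of 1 tested with DESeq2), 2 fell when adjusted over the list alone and all 3 with the block, among them Tyrobp at -2.08 (blocked value 0.00322). Their median was -0.98, and -0.58 with quantile normalisation or -0.90 with centring (adjusted p = 0.0429, and adjusted p = 0.38 with an estimated correlation). The vascular genes Slc2a1 and Rgs5 were at -0.22 and -0.47, and Bpgm, an enzyme of red blood cells, at -0.22, none of them called.

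Of 6 ependymal and choroid plexus genes, Clic6, a chloride channel protein, fell by 1.62 (adjusted p = 0.0213, but 0.0737 with edgeR) and the list test gave adjusted p = 0.184. Ttr, transthyretin of the choroid plexus, was at -2.80 ± 0.69 (adjusted p = 0.0736, blocked value 0.000269), and Dynlrb2 and Rsph1, proteins of motile cilia, were at 1.47 (blocked value 0.0133) and 0.94 (blocked value 0.0256). Adjusted over the list alone, 1 gene rose and 4 fell. Of 7 striatal genes, Ppp1r1b, the dopamine-regulated phosphoprotein DARPP-32, fell by 2.44 (adjusted p = 0.0284), 2 fell when adjusted over the list alone, and the list test gave adjusted p = 0.184. Among 4 genes of cortex, hippocampus or thalamus, Emx2 rose, Rorb, a nuclear receptor, fell by 1.62 (adjusted p = 0.0418), 2 rose and 1 fell when adjusted over the list alone, and the list test gave adjusted p = 0.184. Lhx9 joined with the block at 0.85 (0.0318). Of 7 hypothalamic transcription factors, Fezf1 rose; Lhx1 at 1.27 (blocked value 0.019) and Nkx2-1 at -1.31 (blocked value 0.0111) were called with the block only. Adjusted over that list alone 2 rose and 1 fell, and the list test gave adjusted p = 0.184.

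Of 16 pan-neuronal genes, none passed in limma (2 at unadjusted p under 0.05; 0 with edgeR and 0 of 7 tested with DESeq2) and 1 fell when adjusted over the list alone; the median was -0.16, which was -0.42 with quantile normalisation and -0.08 with centring, and the list test gave adjusted p = 0.294. Map2, a dendritic microtubule protein, at -1.05 (blocked value 0.0107), and Nefm, a neurofilament, at -1.20 (blocked value 0.00298), were called with the block. No immediate early gene of 11 passed (2 at unadjusted p under 0.05; 0 with edgeR and 0 of 7 tested with DESeq2), also when adjusted over the list alone, and the list median was 0.28 (adjusted p = 0.0596). Among 81 nuclear genes of oxidative phosphorylation 74 lay above 0, at a median of 0.69 (adjusted p = 4.25e-15, and adjusted p = 0.38 with an estimated correlation), while none passed singly in limma (34 at unadjusted p under 0.05; 0 with edgeR, 10 of 49 tested with DESeq2). Per pair their median was 0.42 and 0.90 in the PACAP line and 0.32 and 1.20 in the BDNF line, so it was higher in both pairs of number 2. Adjusted over the list alone, 8 rose; with the block 35 rose, such as Ndufa13, a complex I subunit, at 1.13 ± 0.24 (blocked value 0.00704), and Cox6a2 was lower. The 74 ribosomal protein genes had a median of 0.02, which was -0.26 with quantile normalisation and 0.10 with centring, and none passed (6 at unadjusted p under 0.05; 0 with edgeR, 2 of 40 tested with DESeq2), also when adjusted over the list alone, with adjusted p = 0.184 for the list. With the block 3 were higher and 2 lower. Many of these genes have processed copies whose reads the authors' counting could split. The noncoding nuclear transcript Snhg11 changed by -3.30 ± 0.45 (adjusted p = 0.0109).

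**Figure D3:**
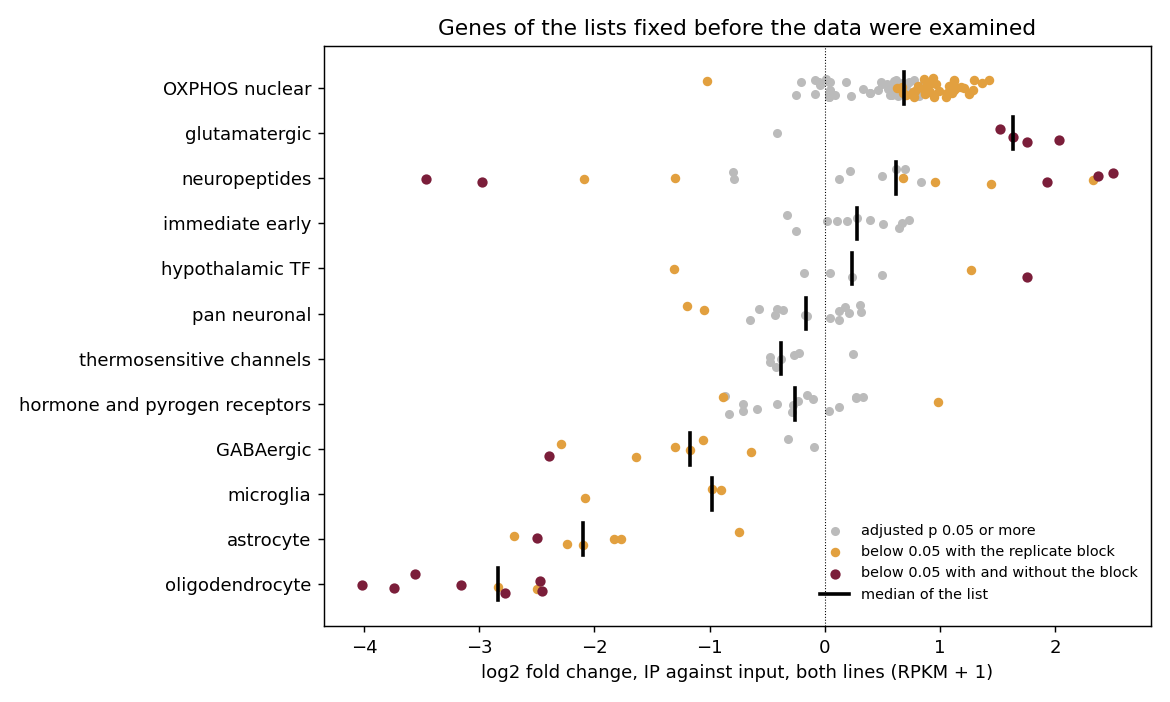
Joint log2 change (immunoprecipitate minus input) of each measured member of 12 gene lists, with a bar at the list median; dark points passed with and without the block, orange points with the block only and grey points in neither. Of the 12 lists shown, oligodendrocyte members lie lowest at a median of -2.84 and glutamatergic members highest at 1.64; the oligodendrocyte precursor list, at -3.18, is not shown.

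Rpl10a encodes the ribosomal protein L10a, which carries the GFP tag per the labels, so its reads may include transcripts of the tagged copy. It was measured at 1768 RPKM in PACAP input 1 and 10184 RPKM in PACAP immunoprecipitate 1, at 922 and 2800 RPKM in the second PACAP pair, at 1539 and 6359 RPKM in the first BDNF pair, and at 540 and 501 RPKM in the second BDNF pair. The log2 ratios were 2.53, 1.60, 2.05 and -0.11, and the joint change was 1.52 ± 0.80 (adjusted p = 0.326, blocked value 0.02). None of the other 74 ribosomal protein genes reached its ratio in the first pair of either line, 1 did in the second PACAP pair and 62 did in the second BDNF pair.

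The joint test called 171 genes, 40 higher and 131 lower. With the block 1207 genes passed, 546 higher and 661 lower, and all 171 were kept. Within replicate number 1, fitted alone on its 4 libraries, 175 genes were higher and 278 lower; within number 2, 717 were higher and 425 lower. The counts became 51 higher and 96 lower with quantile normalisation, and 40 higher and 81 lower with libraries centred on the median. Without PACAP input 1 the count was 39, without PACAP input 2 it was 44, without PACAP immunoprecipitate 2 it was 63, without BDNF input 1 it was 59, without BDNF input 2 it was 48 and without BDNF immunoprecipitate 2 it was 34.

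In the PACAP line, 2 immunoprecipitates against 2 inputs, 4 genes rose and 19 fell. Gng8 rose by 3.52 ± 0.49 (± SE, adjusted p = 0.0325), Nxph4 by 2.98 ± 0.39 (adjusted p = 0.0266), Ucn3 by 2.81 ± 0.44 (adjusted p = 0.0434) and Samd3 by 2.44 ± 0.35 (adjusted p = 0.033). The genes that fell included those of myelin and glia: Mobp changed by -3.89 ± 0.35 (adjusted p = 0.00582), Fa2h, which hydroxylates myelin lipids, by -3.84 ± 0.42, Olig2 by -3.87 ± 0.60, Ermn by -3.73 ± 0.55, Fabp7 by -3.66 ± 0.52 and Qk, an RNA-binding protein of glia, by -3.65 ± 0.56. Efhd1 changed by -4.23 ± 0.47, Zfp36l1, an RNA-decay factor, by -4.04 ± 0.62, Gatm, an enzyme of creatine synthesis, by -4.03 ± 0.58, and Lrrc17 by -3.79 ± 0.39.

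Further genes were higher in the PACAP immunoprecipitates at an unadjusted p under 0.05 and passed with the block. They were Adcyap1 at 2.43 ± 0.57 (adjusted p = 0.168, blocked value 0.00374), Bdnf at 2.31 ± 0.53 (0.155; 0.0114), Crhbp, the binding protein of corticotropin-releasing hormone, at 2.30 ± 0.41 (0.0783; 0.00866), Gchfr, a regulator of tetrahydrobiopterin synthesis, at 2.30 ± 0.75 (0.277; 0.0131), Efcab10 at 2.25 ± 0.55 (0.171; 0.0185) and Nme4, a mitochondrial nucleoside diphosphate kinase, at 2.06 ± 0.56 (0.204; 0.034). Rpl10a was at 2.06 ± 1.13 (0.489; 0.0477). With a block shared by both lines Gchfr (0.0523), Nme4 (0.0629) and Rpl10a (0.056) were not called.

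Camera called 7 lists in this line, and each lost its call with an estimated correlation. The oligodendrocyte list had a median of -3.14 (adjusted p = 7.22e-14, and adjusted p = 0.325 with an estimated correlation), with 3 members lower (Mobp, Fa2h, Ermn), and all 9 when adjusted over the list alone or with the block. The astrocyte median was -2.19 (adjusted p = 8.34e-06, and adjusted p = 0.396 with an estimated correlation), with no single call in limma (6 at unadjusted p under 0.05; 0 with edgeR, 4 of 4 tested with DESeq2), 5 lower when adjusted over the list alone and 6 with the block, such as Sox9, a glial transcription factor, at -2.64 (blocked value 0.00308). The GABAergic median was -1.56 (adjusted p = 0.000225, and adjusted p = 0.396 with an estimated correlation), with no single call (5 at unadjusted p under 0.05; 0 with edgeR, 1 of 5 tested with DESeq2), 4 lower when adjusted over the list alone and 5 with the block, Dlx5 at -3.28 among them (blocked value 0.000511). The glutamatergic median was 1.51 (adjusted p = 7.2e-05, and adjusted p = 0.325 with an estimated correlation), with no single call (4 at unadjusted p under 0.05; 0 with edgeR, and DESeq2 tested 0 of them), 4 higher when adjusted over the list alone and 3 with the block. Neuropeptide genes had a median of 0.87 (adjusted p = 0.00444, and adjusted p = 0.396 with an estimated correlation), with Ucn3 called, 3 higher and 2 lower when adjusted over the list alone, and 5 higher and 2 lower with the block. The microglial median was -1.46 (adjusted p = 0.0293, and adjusted p = 0.396 with an estimated correlation) and that of the genes of oxidative phosphorylation 0.66, and 0.41 with quantile normalisation or 0.74 with centring (adjusted p = 1.77e-11, and adjusted p = 0.407 with an estimated correlation).

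The PACAP count of 23 became 327 with the block, 105 higher and 222 lower, and kept all 23. Mobp stayed called in each of 8 fits that left out 1 library, and the count was 3 without PACAP input 1, 11 without PACAP immunoprecipitate 1, 1 without PACAP input 2, 3 without PACAP immunoprecipitate 2, and 10 without either BDNF input. The Gng8 call ended without PACAP immunoprecipitate 1 (adjusted p = 0.0772), PACAP input 2 (0.146) or PACAP immunoprecipitate 2 (0.157), and that of Lrrc17 without PACAP input 1 (0.0544) or PACAP input 2 (0.132). Efhd1, Fa2h and Fabp7 were lost without PACAP input 1 (0.0896, 0.0862 and 0.171), PACAP input 2 (0.132, 0.132 and 0.181) or PACAP immunoprecipitate 2 (0.101, 0.0926 and 0.177). Nxph4, Samd3, Zfp36l1, Gatm, Olig2, Ermn and Qk were lost without each PACAP library and each BDNF input, with highest adjusted p-values of 0.181, 0.205, 0.284, 0.205, 0.299, 0.205 and 0.284. Ucn3 ended in all 8 (highest 0.303), and also with a pseudocount of 0.1 (0.124), a filter at 5 RPKM (0.0934), library weights (0.0748) and the libraries of its line alone (0.0852). A pseudocount of 0.1 ended the calls of Zfp36l1 (0.0729), Gatm (0.0581), Olig2 (0.0869), Ermn (0.0729), Fabp7 (0.0985) and Qk (0.0687), and the filter at 5 RPKM those of Zfp36l1 (0.0528) and Olig2 (0.0547). With edgeR on all deposited counts 3 genes were called, and of the 14 genes named as called only Fa2h passed.

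In the BDNF line, 5 genes fell and none rose in limma (726 at unadjusted p under 0.05 in both directions; 0 with edgeR on all counts, 27 with DESeq2 on the genes with proportional counts). Mobp changed by -3.23 ± 0.35 (adjusted p = 0.0233), Efhd1 by -3.68 ± 0.47 (adjusted p = 0.0416), Lrrc17 by -3.49 ± 0.39 (adjusted p = 0.0233), Csrp1, a LIM-domain protein, by -2.72 ± 0.31 (adjusted p = 0.0233) and Tmem88b by -2.58 ± 0.33 (adjusted p = 0.0416). At an unadjusted p under 0.05, Gng8 was at 3.15 ± 0.49 (adjusted p = 0.106, blocked value 0.00145), Adcyap1 at 2.58 ± 0.57 (0.286; 0.00567), Samd3 at 2.40 ± 0.35 (0.0789; 0.00354), Meig1 at 2.35 ± 0.52 (0.286; 0.0395, but 0.0564 with a block shared by both lines), Emx2 at 2.10 ± 0.45 (0.28; 0.0226), C1ql1 at 2.08 ± 0.64 (0.488; 0.017), Nrn1 at 2.05 ± 0.35 (0.139; 0.011) and Fezf1 at 2.01 ± 0.40 (0.223; 0.0334). Efcab10 at 1.88 ± 0.55 (0.476) and Pcsk1, prohormone convertase 1, at 1.76 ± 0.46 (0.442) did not pass with the block (0.0693 and 0.0775). Bdnf itself was at 1.54 ± 0.53 (adjusted p = 0.529, blocked value 0.103) and Rpl10a at 0.97 ± 1.13 (adjusted p = 0.874).

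Lower at an unadjusted p under 0.05 were Pwwp2a at -3.83 ± 0.63 (adjusted p = 0.139, blocked value 0.00377), Ermn at -3.75 ± 0.55 (0.0789; 0.00354), Snhg11 at -3.36 ± 0.64 (0.212; 0.0156) and Olig1 at -3.33 ± 0.74 (0.286; 0.0021). Camera called 5 lists. The oligodendrocyte median was -2.54 (adjusted p = 2.22e-14, and adjusted p = 0.318 with an estimated correlation), with Mobp lower singly, and all 9 when adjusted over the list alone or with the block. The astrocyte median was -1.65 (adjusted p = 2.61e-06, and adjusted p = 0.381 with an estimated correlation), with 4 lower when adjusted over the list alone, and the GABAergic median -0.93 (adjusted p = 0.00261, and adjusted p = 0.381 with an estimated correlation). The glutamatergic median was 1.56 (adjusted p = 1.1e-06, and adjusted p = 0.216 with an estimated correlation), with 4 higher when adjusted over the list alone and 3 with the block. Genes of oxidative phosphorylation had a median of 0.73, and 0.46 with quantile normalisation or 0.80 with centring (adjusted p = 2.05e-15, and adjusted p = 0.381 with an estimated correlation). With the block, camera also called the microglial list at -0.89, a median of -0.53 with quantile normalisation and -0.82 with centring (0.0476), the hypothalamic transcription factors at 0.62 (0.033), both with adjusted p = 0.456 with an estimated correlation, and the ribosomal proteins at 0.11, a median of -0.22 with quantile normalisation and 0.18 with centring (0.0484, and adjusted p = 0.69 with an estimated correlation).

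The BDNF count of 5 became 111 with the block, 31 higher and 80 lower, and kept all 5. It was 3 without either PACAP immunoprecipitate and 0 without BDNF input 1, BDNF input 2 or BDNF immunoprecipitate 2; it was 8, with 1 higher and 7 lower, with quantile normalisation. The calls of Mobp, Lrrc17, Csrp1 and Efhd1 ended without BDNF input 1 (adjusted p = 0.23, 0.23, 0.23 and 0.256), BDNF input 2 (0.318 each) or BDNF immunoprecipitate 2 (0.391 each). Without BDNF immunoprecipitate 1, Lrrc17 (0.0669) and Csrp1 (0.0537) were lost as well, and Efhd1 was lost without each PACAP library in turn (0.0557 to 0.0808). Tmem88b ended in all 8 fits (0.0557 to 0.596). A pseudocount of 0.1 ended the calls of Efhd1 (0.241), Lrrc17 (0.18) and Tmem88b (0.0801), the filter at 5 RPKM that of Efhd1 (0.051), and edgeR on all deposited counts all 5 (0.123 to 0.408).

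Over the 8863 genes the changes of the lines correlated at r = 0.738 (Spearman rho = 0.678), and 74.83% had the same sign; the comparisons share no libraries, and genes are not independent replicates. Between single pairs, r was 0.523 within the PACAP line and 0.45 within the BDNF line. Across the lines it was 0.601 and 0.561 for pairs with the same replicate number and 0.614 and 0.428 for pairs with the other. All 5 genes that fell in the BDNF line, such as Mobp and Efhd1, also fell in the PACAP line, where 0.01 would be shared by independent lists. The calls of both lines, with and without the block, used the same spread per gene from all libraries, however. A gene with a small spread was thus favoured in both lines, so the numbers for independent lists are no fair reference. With the block, 23 genes rose in both lines (105 and 31 calls; 0.37 for independent lists), Gng8 and Adcyap1 among them, and 72 fell in both (222 and 80 calls; 2 for independent lists), Mobp among them; 0 genes were called in opposite directions.

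Whether enrichment differed between the lines was tested as the PACAP change minus the BDNF change. No gene passed in limma, with or without the block (58 and 224 at unadjusted p under 0.05), nor with edgeR on all deposited counts, and DESeq2 on the genes with proportional counts called 1 lower. Among genes of at least 5 RPKM the largest unadjusted difference was that of Oxt, the gene of oxytocin, at 3.65 ± 0.98 (adjusted p = 1), with ratios of 2.00 and 0.05 in the PACAP pairs and -1.83 and -3.41 in the BDNF pairs. Crhbp differed by 2.02 ± 0.58 and Pcdhga3, a gamma protocadherin whose constant exons are shared with its neighbours, by 2.13 ± 0.61. On the lower side were Vax1, a homeodomain factor of the ventral forebrain, at -2.46 ± 0.82, Fezf2, a forebrain zinc-finger factor, at -1.97 ± 0.83, and Akap12, a scaffold of protein kinase A, at -1.82 ± 0.56, all with unadjusted p under 0.05 and adjusted p = 1. Adcyap1 differed by -0.15 ± 0.81, Bdnf by 0.78 ± 0.74 and Rpl10a by 1.09 ± 1.60. Camera called the neuropeptide list, with a median of 0.39 (adjusted p = 0.0168, and adjusted p = 0.885 with an estimated correlation), and the oligodendrocyte list, with a median of -0.59 (adjusted p = 0.0202, and adjusted p = 0.885 with an estimated correlation). With the block it also called the GABAergic list at -0.22 and the oligodendrocyte precursor list at -0.54 (0.0445 each, and adjusted p = 0.812 with an estimated correlation). Without the first BDNF pair the oligodendrocyte median was 0.15 and the GABAergic median 0.13, and without the second PACAP pair the neuropeptide median was -0.06. Between pairs of number 1 alone the oligodendrocyte, GABAergic and precursor medians were -1.15, -0.89 and -1.37, and between pairs of number 2 they were -0.17, 0.12 and -0.10.

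The inputs of the lines were set against each other to see whether the tissue differed before the pull-down, 2 libraries against 2. No gene passed in limma (25 at unadjusted p under 0.05; 0 with edgeR and with DESeq2), also with the replicate number as one term for both lines (138 at unadjusted p under 0.05). At an unadjusted p under 0.05 (each with adjusted p = 1), Oasl2, an interferon-induced gene, was at 1.99 ± 0.77 in the PACAP inputs relative to the BDNF inputs and Eif3j1, a translation initiation factor subunit, at 1.25 ± 0.38. Lower were Eno1b, a copy of the enolase gene whose reads the counting could split, at -2.97 ± 0.82, Sumf2 at -2.02 ± 0.42, Tuba1c, an alpha tubulin with close paralogs, at -1.77 ± 0.74 and Cdk5rap2, a centrosomal protein, at -1.43 ± 0.45. Adcyap1 was at -0.45 ± 0.57 and Bdnf at -0.06 ± 0.53. Ribosomal protein genes lay above 0 in 70 of 74 cases, at a median of 0.23 (adjusted p = 1.67e-07, and adjusted p = 0.892 with an estimated correlation), or -0.12 without PACAP input 1 and -0.27 without BDNF input 2. Camera also called the ependymal and choroid list at 0.46 (adjusted p = 0.00257, and adjusted p = 0.369 with an estimated correlation) and the immediate early genes at 0.23 (adjusted p = 0.0305, and adjusted p = 0.496 with an estimated correlation), a call that ended with the replicate term. Between inputs of number 1 alone these 3 medians were 0.09, 0.64 and 0.45, and between those of number 2 they were 0.40, 0.06 and -0.01.

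Between the immunoprecipitates, 1 gene passed, the gene model Gm7429, lower in the PACAP line at -4.71 ± 0.48 (adjusted p = 0.0256) and at -3.52 ± 0.48 between the inputs (adjusted p = 0.296); it was chosen after its values were seen. The count was 0 without PACAP immunoprecipitate 1, BDNF immunoprecipitate 1 or BDNF immunoprecipitate 2, and 2 without either BDNF input. Oxt was at 5.07 ± 0.69 (adjusted p = 0.164), with 72.8 and 25.1 RPKM in the PACAP and 0.10 and 0.56 RPKM in the BDNF immunoprecipitates. It was already higher in the PACAP inputs, at 17.4 and 24.25 RPKM, than in the BDNF inputs, at 2.92 and 15.53 RPKM. Oxt passed with the replicate number as a block shared by both lines (0.0469), as did Ifit1, an interferon-induced gene, at 3.04 ± 0.84 (0.0469). Oasl2 was at 3.47 ± 0.77 and Gal, the gene of galanin, at 1.74 ± 0.68, both with adjusted p = 1. Lower were Eno1b at -2.84 ± 0.82, Pvalb, the calcium-binding protein parvalbumin, at -2.58 ± 0.84, Cdk5rap2 at -2.19 ± 0.45 and Dlx5 at -1.61 ± 0.69, all unadjusted and with adjusted p = 1. The neuropeptide list lay at 0.49 (adjusted p = 0.000174, and adjusted p = 0.706 with an estimated correlation), the GABAergic list at -0.63 (adjusted p = 0.0037, and adjusted p = 0.707 with an estimated correlation) and the oligodendrocyte list at -0.62 (adjusted p = 0.000174, and adjusted p = 0.707 with an estimated correlation). Adjusted over the list alone, 1 neuropeptide gene was higher and 1 oligodendrocyte gene lower. Without BDNF immunoprecipitate 1 the medians were 0.20, -0.05 and -0.03 in that order. Between the libraries of number 1 alone they were 0.56, -1.33 and -1.13, and between those of number 2 they were 0.27, -0.07 and -0.20, so the lower GABAergic and oligodendrocyte values rested mainly on number 1.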

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

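Of the tests in this part, those of a single pair of libraries, a failed immunoprecipitation, an exchange of libraries, sequencing depth and gene span were chosen only after the result was seen.

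Among 21 genes with ratios in 4 pairs, 2 had a pair set far apart from the other 3, where chance would mark about 1 in 20. Fezf1 had its lowest ratio, 0.91, in the second PACAP pair. Efhd1 had its least negative ratio, -3.17, in the first BDNF pair. The difference of the lines' enrichments, tested by camera, marked the neuropeptide list, with a median of 0.39, and the oligodendrocyte list, with a median of -0.59. Both lost the call with an estimated correlation (adjusted p = 0.885 for each).

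The oligodendrocyte genes were lower in the PACAP than in the BDNF enrichment. Without the first BDNF pair the median difference of the 9 genes was 0.15, so the difference may come from that pair rather than from the line. Unbound input RNA carried into that immunoprecipitate is a candidate cause: the oligodendrocyte genes kept a median of 23.3% of their input level there and 4.59% in the other pairs, and the share needed, worked out gene by gene, had a median of 16.3%. By the bound set beforehand it was not excluded, as 3 genes of 3265 lay under 8.16%. A share carried over would lift every gene, however, so these leave room for a share of 7.25% at most. Ttr had a ratio of 7.72%, Efhd1 8.04%, Gnrh1 8.17%, S100b 10.11% and Apoe 13.8%, all below the 16.3% needed. These values argue against carry-over as the whole cause, while a part played by it stays open. A difference between the lines was not tested apart from these pairs and stays open.

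Rpl10a was not higher in the second BDNF immunoprecipitate. A failed pull-down is argued against by the oligodendrocyte genes of that pair, at a median of -3.44, and a counting error by the deposited Rpl10a count of 978. The counts of Rpl10a were not proportional to its RPKM over the libraries, however. What that count holds was thus not established, which limits the argument on counting error. An exchange of input and immunoprecipitate is argued against by r = 0.67 over genes between that pair and the mean of the other 3. No biological explanation was tested, and the expression of the tagged copy in that library stays open.

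Replicate numbers differed in 1743 genes. Depth is argued against, since the BDNF immunoprecipitates, whose second library was the shallower, differed like the other groups (r = 0.50). Gene span as a cause in all groups is argued against by a rho of 0.008 in the BDNF immunoprecipitates, though it was 0.29 and 0.31 in the inputs, where it stays open. A different part of the preoptic area dissected could contribute: the neuropeptide genes differed between input numbers by a median of 0.67, against 0.38 in random lists of like expression (percentile 99.48). Avp, which differed most, was at 2.35 and 2.17 RPKM in the first inputs and 42.1 and 20.5 RPKM in the second. Nucb2 hardly differed (-0.13 and 0.02), and Cartpt went opposite ways in the PACAP and BDNF inputs (-1.27 and 0.37). The random lists were drawn gene by gene and matched on mean expression alone. Whether neuropeptide genes vary more between any libraries was not tested, so the percentile cannot decide for dissection.

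In a plain comparison of 4 against 4 libraries, the split by fraction called 617 genes. Of the 35 splits 2 called as many: that split itself and the split by replicate number, at 845 genes. By the bound set beforehand chance was thus not excluded by this count. The split by replicate number follows the batch and is no random grouping, however, so the count cannot decide. Each of the remaining splits called 0 or 1 gene. The 845 genes point to the batch structure of the samples. With the block the joint count was 1207, and within number 1 alone 175 genes were higher and 278 lower, within number 2 717 and 425. The 8 splits that part all pairs are too few for a share under 0.05; the real split called 1591 genes (1 of 8 reaching that count) and the highest other 0.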

How the results depend on the processing

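The block shared by both lines, the tests on counts and limma on the genes with proportional counts were chosen only after the result was seen. Leaving out 1 library left some groups with a lone sample, which is assumed to vary like the other groups. No gene failed the 1 RPKM filter, so leaving it off moved nothing and tests nothing. The cause of the changes below was not tested.

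The PACAP count of 23 became 13 with a pseudocount of 0.1, 327 with the block and 403 with the shared block. On the genes with proportional counts it was 15 with limma, 4 with edgeR and 110 with DESeq2, and with edgeR on all deposited counts it was 3. The BDNF count of 5 became 2 with a pseudocount of 0.1, 8 with quantile normalisation, 9 with the 4 libraries of the line alone, 111 with the block and 78 with the shared block. It was 3 with limma, 2 with edgeR and 27 with DESeq2 on the genes with proportional counts, and 0 with edgeR on all counts. The joint count of 171 became 1207 with the block and 1462 with the shared block, and on the same tools 44, 36, 288 and 76. The difference of the enrichments, 0 in limma, was 1 with DESeq2. Between the immunoprecipitates the count of 1 became 0 with library weights, 3 with the shared block, 0 with limma and 0 with edgeR on the genes with proportional counts, 3 with DESeq2 and 0 with edgeR on all counts. Between the inputs each of these gave 0.

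Leaving out each library gave 1 to 31 genes in the PACAP line, 0 to 6 in the BDNF line, 34 to 136 jointly and 0 to 2 between the immunoprecipitates. The correlation of the lines' changes, 0.738, ran from 0.527 without PACAP immunoprecipitate 1 to 0.758 without PACAP immunoprecipitate 2, and was 0.607 without PACAP input 2, 0.618 without BDNF input 1 and 0.559 without BDNF immunoprecipitate 2.

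Camera called 7 lists in the PACAP line, 5 in the BDNF line, 6 jointly, 2 for the difference, 3 between the inputs and 3 between the immunoprecipitates; with an estimated correlation it called 0 in each, and also 0 in each with that correlation and the block. With fry the counts were 2, 1, 4, 0, 0 and 0. With the block at the preset correlation the BDNF count was 8 and that of the difference 4.

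Over the named genes, 1110 values under the alternatives were like the first ones, 177 were weaker, 55 were stronger and 1 was reversed. Reversed was Rpl10a in the BDNF line, at -0.86 without BDNF immunoprecipitate replicate 1, the lowest of its leave-one-out values. They reached 2.80 without BDNF immunoprecipitate replicate 2. In the reversed fit, BDNF immunoprecipitate 2 (501 RPKM) was set against BDNF input 1 (1539 RPKM) and BDNF input 2 (540 RPKM). Its own pair was at -0.11, so the reversal may come from the batch.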

Other observations

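The 12 gene families in the next paragraph and the genes that differed between the lines in both fractions were chosen only after the result was seen.

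Beyond oxidative phosphorylation, some of these families lay higher in the immunoprecipitates of the joint comparison. Of 74 mitochondrial ribosomal proteins, 66 lay above 0 at a median of 0.51 (camera adjusted p = 2.56e-13; adjusted p = 0.194 with an estimated correlation), with 2 called and 26 with the block. Small nuclear ribonucleoprotein and Lsm proteins were at 0.66 (9.35e-07; 0.194), mitochondrial import at 0.54 (9.34e-06; 0.194), RNA polymerase subunits at 0.50 (8.53e-05; 0.194), proteasome subunits at 0.29 (0.000757; 0.245) and the vacuolar ATPase at 0.25 (0.0119; 0.245), which were 0.07 and 0.09 with quantile normalisation and 0.37 and 0.33 with libraries centred on the median. Replication-dependent histones were at 0.44 (0.0221; 0.245), with 14 of 21 above 0, 1 called higher and 2 lower. On the lower side, all 8 glutamate receptor subunits lay below 0 at a median of -0.65 (0.00221; 0.245) and voltage-gated potassium channels were at -0.57 (0.00896; 0.245), or -0.31 with quantile normalisation and -0.50 with centring. Zinc finger proteins were at -0.16 (0.0459; 0.324), which turned to 0.03 with quantile normalisation and was -0.08 with centring. GABA receptor subunits at -0.15 (0.255) and gamma protocadherins at 0.17 (0.123), which were at 0.64 with quantile normalisation and 0.24 with centring, were not called.

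At an unadjusted p under 0.05, 9 genes differed between the lines in both fractions, all with the same sign. Oasl2 was at 1.99 between the inputs and 3.47 between the immunoprecipitates, Eif3j1 at 1.25 and 1.69, Fgf18 at 1.08 and 1.06, Cdk5rap2 at -1.43 and -2.19 and Plvap at -1.03 and -0.88. Eno1b at -2.97 and -2.84 and Tuba1c at -1.77 and -2.09 have near copies with which the counting could split reads, and are uncertain. Differences that the tissue already shows before the pull-down need no difference in the tagged cells.

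The higher values of nuclear genes of oxidative phosphorylation could follow from the short span of these genes, as span and joint change had a rho of -0.30 over 8739 genes. Their median of 0.69 was above that of lists matched on span, at percentile 100 of 10000 lists whose highest median was 0.36. That argues against span as the whole cause, but only with a limit, as the lists were drawn gene by gene. Genes of oxidative phosphorylation may vary together, and their camera call was lost with an estimated correlation. The percentile may therefore overstate how rare such a median is. The length of the messenger RNA was not tested, and a higher content of these messages in the tagged neurons stays open as a hypothesis.

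Noncoding transcripts may be left behind with the unbound RNA because they are not translated. The 12 noncoding genes had a median of -0.48, against -0.07 for 8259 protein-coding genes (camera p = 0.00169; p = 0.19 with an estimated correlation), and 11 of them lay below 0. The median was -0.11 with quantile normalisation and -0.40 with libraries centred on the median. Only Snhg11 was called, and 2 were lower with the block. Expression of these transcripts in other cells of the tissue would give the same values and was not tested.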
